A study of Mus musculus with 4 samples.

How the data were processed

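The series holds 4 samples of total RNA from freshly dissected mouse tissue, 1 each of WT trachea, Gemc1-null trachea, WT oviduct and Gemc1-null oviduct. Per the labels' protocols, the tissue was disrupted with beads, RNA was purified on columns, and biotin-labelled sense-strand targets were made and hybridised to 1-colour Affymetrix arrays. The groups were taken from the tissue and genotype in the labels. The labels name no hybridisation or scan batch, and the part of the gene deleted in the null mice is not given in the sources used here.

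The deposited table gives 1 value per probe set and array. Per the submitters' processing notes it was made with RMA, which corrects background, quantile-normalizes the arrays and summarises probes on a log2 scale; the version and settings of RMA are not given in the sources used here. The deposited values carry a second log2: 2 to the power of the value was a number of 6 significant digits in 100% of cells within a relative tolerance of 1e-09, against 0.08% for powers of 10, 0.057% for powers of e and 0.044% for the values themselves. The array medians were 2.56 to 2.59 as deposited. All values below are therefore 2 to the power of the deposited value, read as log2 RMA signal. On that scale the hybridisation controls bioB, bioC, bioD and cre stood at 7.94, 9.42, 11.78 and 13.07 on the WT trachea array and in the same order on the others. No raw probe intensities were used here, so background correction and summarisation stand as deposited. Positive controls exceeded negative controls with an area under the curve of 0.845 to 0.863, and the negative-control median lay between 5.74 and 5.98.

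The table has 72688 probe sets, of which 6732 are controls. Probe sets were named from the platform annotation given for this work, with symbols updated through gene identifiers and synonyms in a RefSeq gene table of assembly GRCm38.p6. Of 65956 transcript clusters 31220 had 1 gene, 1530 listed several genes or were not resolved and stayed unnamed, and 33206 were not listed. The named probe sets gave 30689 genes, 30982 of the probe sets through the RefSeq table and 238 by the annotation's own symbol. Of the genes, 422 had more than 1 probe set, and the probe set with the highest mean over the 4 arrays was used. The genome build behind the array is not given in the sources used here, so no coordinates are printed and the RefSeq table served only for names and for which genes neighbour each other.

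A gene passed the level filter in a tissue where its signal was at or above the array's median over all probe sets (percentile 50) on at least 1 of the tissue's 2 arrays, which left 20154 genes in trachea and 19700 in oviduct. For a named gene given as a fold whose dimmer array lay below that array's negative-control median, the fold is printed as "at least" and taken against that median, a choice made after the values were seen. Within a tissue there was 1 array per group, so genes were counted by size alone, at least 2-fold lower or higher, with no p-value. Overlaps were set against the product of the 2 counts over the number of genes. The tissues were joined in limma with tissue as a block and genotype as the effect, moderated by empirical Bayes and adjusted by Benjamini-Hochberg at 0.05 over 20981 genes that passed in either tissue. This fit has 1 residual degree of freedom, and leaving out an array leaves none, so no leave-one-out fit exists. The fit was tested on simulated data with 20981 genes, of which 200 were changed: it recovered 0 of them at a log2 change of 1, 0 at 2 and 88.5% at 3, the last with 12 false calls. Simulated variances were drawn to differ less between genes than in the real fit, whose prior had 1.77 degrees of freedom. These shares are therefore no measure of its power, and 0 calls do not show that no shared change exists. With the oviduct genotypes exchanged, 201 genes lower and 116 higher had an unadjusted p under 0.05, and 0 passed adjustment. The exchanged fit asks for differences in opposite directions in the 2 tissues and moves a shared change into the residual. Its counts therefore do not calibrate the main fit.

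There were 32 gene lists, fixed with the design before the data were examined: cilia complexes and regulators, pathways, and markers of the cell types the dissected tissue could hold. A list's median difference was set against 10000 random lists of the same size, drawn with replacement from the same 20 bins of mean level; the percentile describes these arrays and is no test. In a check on 200 random lists of 18 genes in oviduct, 6.5% fell outside the central 95%, and a list shifted by a log2 of 1 was below every random list. Lists with fewer than 3 members past the filter are given as values. Named genes followed a rule fixed at the same time: all measured regulators; per tissue the 8 largest differences in each direction past 2-fold; per list and tissue the 3 members with the largest absolute difference; and the 8 smallest p-values per direction of the limma fit. Gene models without a proper name, microRNA, small nucleolar RNA, olfactory and vomeronasal receptor genes and immunoglobulin or T cell receptor segments were left out of the rankings. A few further genes are named for comparison with these.

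The alternatives, also fixed beforehand, were no level filter, a filter at the 75th percentile, re-centred arrays, a repeated quantile normalization, cyclic loess, the mean of a gene's probe sets, every probe set on its own, thresholds of 1.5-fold and 3-fold, and, for the limma fit, no tissue block, an intensity trend, Benjamini-Hochberg 0.1 and an added 2-fold threshold. Random lists that were not matched on level were a further alternative for the list medians. R 4.3.3 with limma 3.58.1 was used for the fits and normalizations, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib for the rest.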

Results

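Transcript levels were measured in whole trachea and whole oviduct of wild-type (WT) mice and of mice labelled null for Gemc1, a gene whose current symbol is Gmnc and whose product, a geminin relative, is known to start the gene programme of multiciliated cells. The series asks, per its title, what part this gene plays in that programme. There were 4 groups with 1 Affymetrix array each: the tracheas came from male mice of 39 days and the oviducts from female mice of 65 days. No group had a replicate, so within a tissue a difference between the 2 arrays carries no replicate check, no test and no error, and the number of arrays limits every value. All levels are log2 RMA signals, and all differences are the array labelled Gemc1-null minus the WT array of the same tissue. Across all probe sets the median level lay between 5.91 and 6.00 on the 4 arrays. Over probe sets the 2 oviduct arrays correlated at r = 0.98 and the 2 trachea arrays at r = 0.943, which is below the r = 0.947 between WT trachea and WT oviduct. Xist, the X-inactivation transcript, stood at 11.49 and 11.67 on the oviduct arrays and at 5.47 and 5.48 on the trachea arrays. The Y-linked genes Kdm5d, Eif2s3y and Uty lay between 7.15 and 7.82 on the trachea arrays and between 4.34 and 4.71 on the oviduct arrays.

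The targeted gene was examined first. Gmnc (NCBI gene 239789) was read by 1 probe set. Its level was 5.90 on the WT trachea array and 4.63 on the trachea array labelled Gemc1-null, both too low to pass the level filter there. In oviduct it was 6.11 on the WT array and 8.86 on the array labelled Gemc1-null, a 6.72-fold higher level that goes against that label. The deleted part of the gene is not given in the sources used here, and a probe set outside it checks nothing, so the arrays are called by their labels throughout and each direction below rests on those labels.

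Among the other regulators of multiciliated cell fate, Myb, a transcription factor of early multiciliated cells, was 5.23-fold lower on the trachea array labelled Gemc1-null and 4.58-fold lower on the oviduct array. Rfx3, a ciliary transcription factor, had differences of -0.94 in trachea and -0.89 in oviduct. Trp73, which encodes p73, differed by -1.02 in oviduct and by 0.17 in trachea. Rfx2 differed by -0.87 in oviduct and -0.19 in trachea. Mcidas, the geminin relative that acts beside Gmnc, differed by -0.56 in trachea and -0.23 in oviduct, and Ccno by -0.78 and -0.32. Ccno stood at 6.72 on the WT array and 5.93 on the other in trachea, and at 6.20 and 5.88 in oviduct. The negative-control medians of the arrays labelled Gemc1-null were 5.74 and 5.79, so background limits the Ccno differences. Foxn4 differed by 0.12 in trachea and -0.52 in oviduct, E2f4 by -0.28 and -0.03, E2f5 by -0.40 and 0.17, Tfdp1 by 0.61 and -0.09, and Gmnn, which encodes geminin, by 0.23 and -0.11. Foxj1 shared its probe set with another gene and is not reported by name. In trachea 1 of 11 members that passed the filter was at least 2-fold lower and 0 were higher (list median -0.28, percentile 3.04 among 10000 random lists matched on mean level). In oviduct 2 of 12 were at least 2-fold lower and 1, Gmnc itself, was higher (median -0.28, with 1 of 10000 random lists as low).

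**Figure D1:**
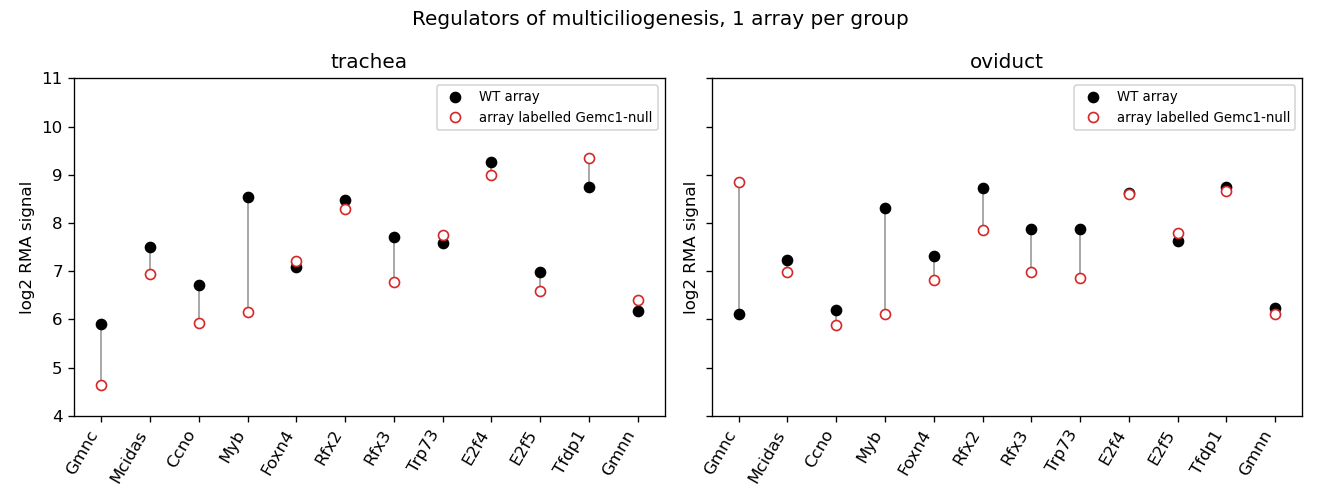
Level (log2 RMA signal, y axis) of the 12 measured regulators of multiciliogenesis (x axis) on the WT array (filled points) and the array labelled Gemc1-null (open points) of each tissue, 1 array per group and so no error bars. Myb is lower on the array labelled Gemc1-null in both panels, and Gmnc goes from 6.11 to 8.86 in oviduct.

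The trachea comparison asks which transcripts differ in an airway, where multiciliated cells sit beside secretory and basal cells. Genes of motile cilia were lower on the array labelled Gemc1-null, and so were airway secretory genes, while genes of skeletal muscle and of squamous epithelium were higher. Of 20154 genes that passed the level filter, 1562 (7.75%) were at least 2-fold lower and 1273 (6.32%) at least 2-fold higher. The 8 largest measured differences below 0 were those of Bpifa1 (125-fold) and Bpifb1 (48.6-fold), airway surface proteins, the secretoglobin Scgb3a1 (55.5-fold), the antimicrobial lectin Reg3g (at least 37.5-fold), Ucp1 (at least 25.3-fold), the uncoupling protein of brown fat, A2ml1 (at least 31.5-fold), Sec14l3 (43.6-fold) and Sftpc (at least 29.1-fold), a surfactant protein. The 8 largest above 0 were those of Tgm3 (at least 67.4-fold higher), Krtdap (at least 61.4-fold) and Serpinb3a (at least 28.4-fold), genes of differentiating keratinocytes, and of the muscle genes Myot (at least 46.1-fold), Myh1 (at least 86.7-fold), Myh8 (at least 65.8-fold), Neb (at least 83.9-fold) and Atp2a1 (92.2-fold). Here and for the oviduct, "at least" marks a gene whose dimmer array lay below its negative-control median, which then took the place of the measured level, and no order is read among such genes. The counts rest on 1 array per group, and they were 2689 lower and 2384 higher at a 1.5-fold threshold, 873 and 615 at 3-fold, with 2582 lower when every probe set was counted on its own.

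Within the motile cilia lists, 16 of 18 axonemal dynein genes were at least 2-fold lower in trachea (median -1.90), among them Dnah6 at -4.27, Dnah12 at -4.20 and Dnah3 at -3.92. The closely related Dnah7a and Dnah7c (-2.01 and -2.23) are uncertain as separate genes. Of 18 dynein arm assembly and docking genes 13 were at least 2-fold lower (median -1.24), including Ccdc39 at -2.53, Lrrc6 at -2.51 and Dnaaf3 at -1.88. Radial spoke and central pair genes followed with 12 of 15 (median -2.31), among them Rsph4a at -3.74, Hydin at -3.57 and Nme5 at -3.16. Of 32 tektins and other proteins of ciliated cells, 27 were at least 2-fold lower (median -1.85), including Sntn at -4.74, Cfap65 at -3.88 and Cfap44 at -3.56. No member of these 4 lists was at least 2-fold higher, and for each list 0 of 10000 random lists had a median as low. The centriole amplification list had a smaller shift (3 of 19 at least 2-fold lower, median -0.50), with Deup1 at -1.50, Cetn4 at -1.43 and Ccdc78 at -1.13. Deup1 lay below the negative-control median on the array labelled Gemc1-null. Against that median it was at least 1.58-fold lower, a bound short of 2-fold. Intraflagellar transport and BBSome genes, which primary cilia use too, had 3 of 33 members at least 2-fold lower (median -0.47), with Traf3ip1 at -1.49, Wdr19 at -1.04 and Ift88 at -1.03. On the array labelled Gemc1-null the 83 motile cilia genes that passed the filter had a median level of 5.72, beside a negative-control median of 5.74, so that background limits their measured differences.

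Markers of other cells and tissues differed between the same 2 trachea arrays. Members counted here as lower or higher are those at least 2-fold lower or higher. The airway secretory list was lower in 12 of 13 members (median -4.35), among them Bpifa1, Scgb3a1 and Reg3g. General epithelial genes were lower in 7 of 9 (median -1.38), led by Krt8 at -3.04, Krt18 at -2.69 and Krt19 at -1.84. Basal cell genes were higher in 6 of 9 members (median 1.25), with Krt14 at 3.78, Krt5 at 3.02 and Trp63 at 2.11. Skeletal muscle genes were higher in 9 of 9 (median 4.53), among them Myh1 at 6.89, Atp2a1 at 6.53 and Myh4 at 5.17, and squamous epithelium genes in 5 of 6 (median 4.27), with Krt13 at 6.43, Krt4 at 6.30 and Sprr3 at 5.01. Lymphocyte genes were lower in 8 of 8 (median -3.33), including Ms4a1 at -4.58, Cd79b at -4.36 and Cd3e at -4.23, and adipocyte genes in 6 of 7 (median -2.50), including Ucp1 at -5.68, Cidea at -2.71 and Fabp4 at -2.63. Smooth muscle genes had a median of -0.92 (3 lower and 1 higher of 8), with Cnn1 at -2.10, Myh11 at -1.53 and Tagln at -1.17. Fibroblast genes had a median of 0.54 with Lum at 1.02, Dpt at 0.84 and Dcn at 0.58, and cartilage genes a median of 0.01, with Chad at -4.47 and Acan at -1.25. Several other cartilage genes read about as high in WT oviduct as in WT trachea (Col2a1 7.21 and 7.54, Comp 6.31 and 6.38), so that the list median says little about cartilage. In trachea, then, differences of the size seen in cilia genes or larger were also found in markers of other cell types.

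The oviduct comparison puts the same question to a tract lined by multiciliated and secretory cells. Motile cilia genes were lower on the array labelled Gemc1-null, genes of epithelium in general differed by under 2-fold, and ovarian genes were lower. Of 19700 genes that passed the filter, 546 (2.77%) were at least 2-fold lower and 159 (0.807%) at least 2-fold higher. The 8 largest measured differences below 0 were those of the steroidogenic genes Cyp11a1 (at least 76.4-fold lower), Hsd3b1 (at least 24.8-fold) and Akr1cl (at least 20.2-fold), besides Sntn (at least 20.6-fold), a protein of ciliary tips, Spata18 (at least 26.3-fold), Dnah6 (at least 15.5-fold), Dnah5 (at least 15.9-fold) and Rgs22. Rgs22 too lay below the negative-control median on the array labelled Gemc1-null, and no fold is given for it. The 8 largest above 0 were those of the chemokine gene Cxcl15 (a log2 difference of 3.82, from background), the water channel Aqp8 (9.12-fold higher), Gmnc (6.72-fold), the gastric lipase Lipf (5.49-fold), Adh7 (5.24-fold), Elapor1 (4.98-fold), Nsg2 (4.76-fold) and the carbonic anhydrase Car12 (4.61-fold). These counts too rest on 1 array per group, and they were 1033 lower and 555 higher at 1.5-fold, 271 and 35 at 3-fold, and 868 and 282 when every probe set was counted on its own.

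In oviduct 15 of 18 axonemal dynein genes were at least 2-fold lower (median -1.87), among them Dnah6 at -4.62, Dnah5 at -4.49 and Dnah12 at -4.46. The assembly and docking list had 11 of 18 (median -1.38), with Ccdc39 at -2.28, Lrrc6 at -2.22 and Zmynd10 at -2.17. Radial spoke and central pair genes had 11 of 15 (median -2.34), with Hydin at -4.13, Rsph4a at -4.05 and Nme5 at -2.60, while Rsph6a stood at 0.24. The tektins and other ciliated cell proteins had 29 of 32 (median -1.86), with Sntn at -5.19, Cfap65 at -4.17 and Cfap44 at -4.09. For each of these 4 lists 0 of 10000 random lists had a median as low, and 0 members were at least 2-fold higher. In the centriole amplification list 2 of 19 were at least 2-fold lower, Cetn4 at -1.54 and Ccdc78 at -1.20, next to Deup1 at -0.95, and the list median of -0.05 was at percentile 6.33 of random lists. Intraflagellar transport and BBSome genes had 0 of 33 past 2-fold (median -0.32, 0 of 10000 random lists as low), with Traf3ip1 at -0.85. The 83 motile cilia genes had a median level of 5.94 on the array labelled Gemc1-null, against a negative-control median of 5.79.

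Epithelial markers in oviduct showed a different picture from trachea. General epithelial genes had 9 of 9 members under 2-fold (median 0.08), with Krt7 at 0.61, Epcam at 0.60 and Krt18 at 0.55. Oviduct secretory genes had 6 of 6 under 2-fold (median 0.38, percentile 99.92), including Muc1 at 0.98, Pax8 at 0.68 and Muc16 at 0.50, and Ovgp1, the oviductal glycoprotein, stood at 12.79 and 12.84. Of the airway secretory list 7 members passed the filter in oviduct and 2 were at least 2-fold higher (median 0.38), Agr2 at 1.43 and Scgb3a1 at 1.16, with Bpifb1 at -0.52. Ovary somatic genes were at least 2-fold lower in 7 of 8 members (median -2.28), among them Cyp11a1 at -6.34, Hsd3b1 at -5.48 and Inha at -4.23, and oocyte genes in 4 of 6 (median -1.42), with Zp2 at -1.97, Zp3 at -1.88 and Bmp15 at -1.56. Zp2, Zp3 and Bmp15 lay below the negative-control median on the array labelled Gemc1-null. Against that median Zp2 was at least 1.63-fold lower, a bound short of 2-fold. Cell cycle genes were at least 2-fold lower in 6 of 20 members and below 0 in all 20 (median -0.72), with Mki67 at -2.22, Kif11 at -1.59 and Ccnb2 at -1.57. Mki67 and Kif11 lay below the negative-control median on the array labelled Gemc1-null. Against that median Kif11 was at least 1.7-fold lower, a bound short of 2-fold. In trachea the cell cycle list had 0 of 21 past 2-fold (median 0.13), with Cdc20 at 0.45, Ccnb2 at 0.35 and Ccna2 at 0.30. Whether the lower cell cycle genes in oviduct share a source with the lower ovary genes was not tested.

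**Figure D2:**
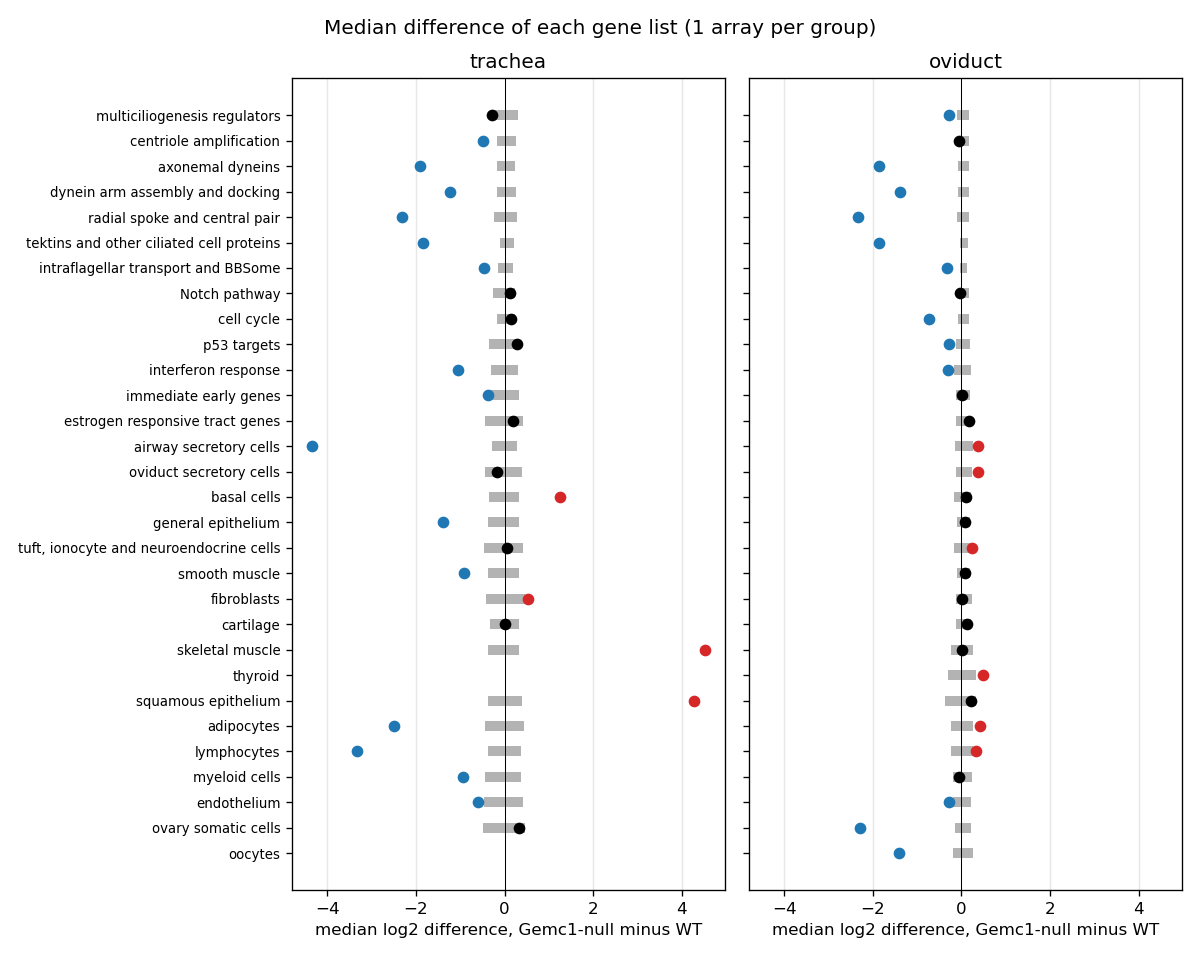
Median log2 difference (array labelled Gemc1-null minus WT, x axis) of each gene list (y axis) in trachea and oviduct; points are list medians from 1 array per group, grey bars the central 95% of the medians of 10000 random lists matched on size and mean level, blue points lie below that range, red above and black within it. The 4 motile cilia lists lie between -1.24 and -2.34 in both panels, whereas skeletal muscle (4.53) and squamous epithelium (4.27) stand out in trachea and ovary somatic cells (-2.28) in oviduct.

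The 2 tissues came from different mice and shared no control, and 18873 genes passed the filter in both. Genes lower in both tissues numbered 251, against 30.6 expected if the tissues were independent, and 63 of them belonged to the 4 motile cilia lists. Of the 83 motile cilia genes 75.9% were at least 2-fold lower in both tissues, against 1.0% of the other genes, which still hold cilia genes outside these lists. Genes higher in both tissues numbered 12, against 6.73 expected, and 0 were in the motile cilia lists. They included Car12, Adcy2, an adenylyl cyclase, Itgb6, an integrin subunit, and Atp6v0a4, a proton pump subunit. A further 72 genes were lower in trachea and higher in oviduct (9.15 expected), and 17 were higher in trachea and lower in oviduct (22.5 expected). Across genes, which are not independent replicates, the differences of the 2 tissues correlated at Pearson r = 0.166 and Spearman rho = 0.0994. The genes lower in both numbered 426 at 1.5-fold and 136 at 3-fold, and those higher in both 82 and 1.

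**Figure D3:**
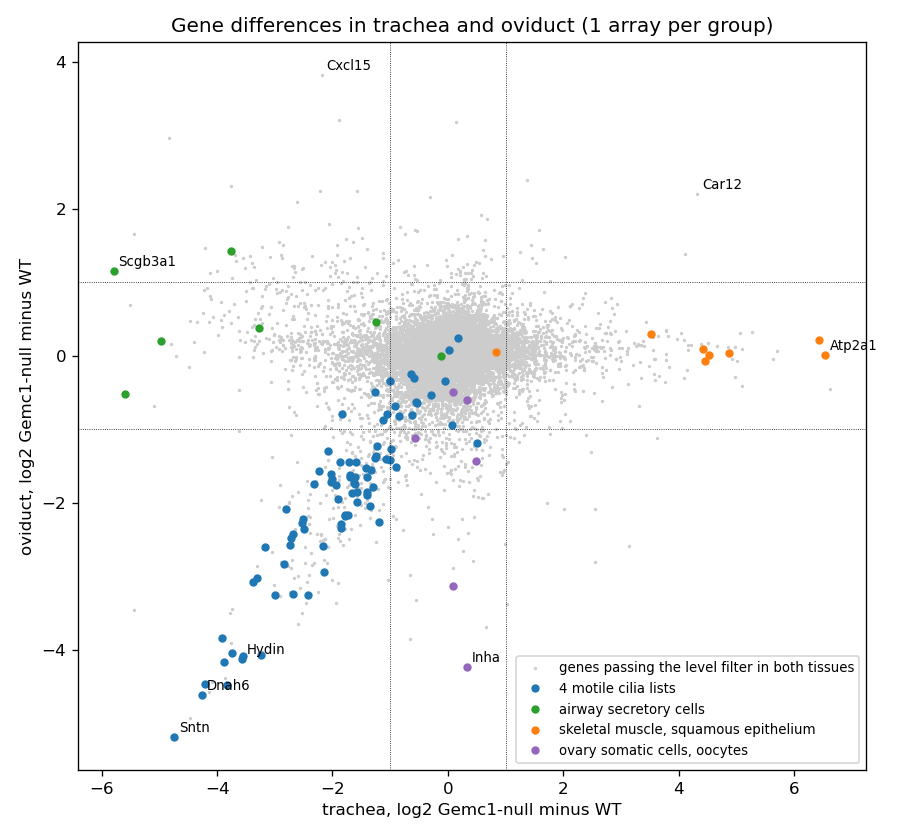
Log2 difference (array labelled Gemc1-null minus WT) in trachea (x axis) and oviduct (y axis) of the 18873 genes that passed the level filter in both tissues (grey), 1 array per group, with members of gene lists coloured and dotted lines at 2-fold. The motile cilia genes (blue) run along the diagonal down to Sntn at -4.74 and -5.19, the muscle and squamous genes lie along the trachea axis, the airway secretory genes lie below 0 in trachea with Agr2 (1.43) and Scgb3a1 (1.16) past 2-fold higher in oviduct, and Inha (0.32 and -4.23) along the oviduct axis.

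A fit over all 4 arrays with tissue as a block (limma, 2 arrays per genotype, 1 residual degree of freedom plus a prior of 1.77) asked for a difference shared by trachea and oviduct; its residual is the disagreement between the tissues. The lowest p-values belonged to the axonemal dyneins Dnah12 (log2 difference -4.33, SE 0.167) and Dnah3 (-3.88, SE 0.150), to Sntn (-4.97, SE 0.199), to the cadherin-related genes Cdhr4 (-3.84, SE 0.154) and Cdhr3 (-4.26, SE 0.181), and to Dnah6, Cfap65 and Spata18, each with a limma adjusted p of 0.509. On the arrays labelled Gemc1-null, Dnah12, Dnah3, Sntn, Dnah6 and Spata18 lay below the negative-control median in both tissues, and Cdhr3 in oviduct. Background therefore limits the differences and SEs of these genes. On the higher side were Adcy2 (1.64, SE 0.153), Atp6v0a4 (1.47), Itgb6 (1.55), Pkhd1l1 (1.40), Arg1 (1.33), which encodes arginase, Snap25 (1.40), Armcx3 (1.16) and Sv2b (1.69), with limma adjusted p-values from 0.540 to 0.80. Atp6v0a4, Itgb6, Pkhd1l1, Arg1 and Sv2b lay below the negative-control median of 5.98 on the WT trachea array. Background limits their differences and SEs too. No gene of the 20981 tested passed Benjamini-Hochberg 0.05 in limma, with 0 lower and 0 higher. At an unadjusted p under 0.05 there were 569 lower and 167 higher, where 1049 would be expected by chance over both directions. With an intensity trend in limma's prior the unadjusted counts were 597 and 175, without the tissue block 450 and 109, and 0 passed adjustment in either.

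For the gene lists fixed before the data were examined, the same p-values adjusted over the list alone gave 16 of 18 axonemal dyneins, 14 of 18 assembly and docking genes, 12 of 15 radial spoke and central pair genes and 31 of 32 tektins and other ciliated cell proteins at 0.05, all of them lower. Over all genes tested the number was 0 in each of these lists. Adjusted over the list alone, 1 of 12 regulators passed (Myb, log2 difference -2.29, limma adjusted p = 0.013), as did 1 of 10 interferon response genes (Usp18, -1.63, limma adjusted p = 0.023), 0 of 19 centriole amplification genes, 0 of 33 intraflagellar transport and BBSome genes and 0 in each of the remaining lists. Part of this call rests on the trachea arrays, on which secretory, muscle and squamous markers differ too.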

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

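The list medians under other normalizations were planned before the data were examined and the test of the genes around Gmnc was set before its result was seen; the other tests in this part were chosen after the values were seen. Some named genes and gene lists differed in opposite directions in the 2 tissues; with 1 array per group the difference between tissues was not tested. Cxcl15 had a log2 difference of -2.19 in trachea and 3.82 in oviduct, and Elapor1 of -3.76 and 2.31. Nsg2 stood at -1.58 in trachea and 2.25 in oviduct, Agr2 at -3.76 and 1.43, Jchain at -1.76 and 1.60, and Scgb3a1 at -5.79 and 1.16. Jchain's dimmer array lay below its negative-control median in both tissues. Against that median Jchain was at least 1.68-fold lower in trachea, a bound short of 2-fold, and at least 2.38-fold higher in oviduct. The airway secretory list had a median of -4.35 in trachea and 0.38 in oviduct, the adipocyte list of -2.50 and 0.41, and the lymphocyte list of -3.33 and 0.33. In oviduct these are shifts of the list, not of most members past 2-fold: 1 of 5 adipocyte genes passed 2-fold there, Cidea, and it was lower in both tissues (-2.71 and -1.08), and 1 of 5 lymphocyte genes, Jchain, was higher.

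The first pattern is a difference in make-up between the 2 trachea arrays: skeletal muscle and squamous epithelium genes were far higher and airway secretory genes far lower on the array labelled Gemc1-null. The pattern stayed under a further normalization: with repeated quantile normalization and cyclic loess the smallest size among these 3 list medians was 4.24. Both were run on values already normalized by RMA, so an artifact of the deposited normalization was not tested. Other tissue in either sample stays open and was not tested apart from the pattern itself: on the array labelled Gemc1-null, where the neighbouring oesophagus is a candidate source, Krt4 reached 13.48 and Atp2a1 12.97, and 9 of 9 muscle and 6 of 7 squamous genes were above the array's median against 5 of 9 and 4 of 7 on the WT array, whereas 7 of 7 adipocyte and 8 of 8 lymphocyte genes were above it on the WT array, with Ucp1 at 10.40, against 3 of 7 and 3 of 8. Whether added tissue also accounts for the lower secretory genes, by taking the place of trachea in the sample, stays open, as does a change of the tracheal lining towards a squamous type, and neither was tested. Whether a smaller share of airway epithelium accounts for the lower cilia genes in trachea cannot be told apart from an effect of genotype. A single array carries both. General epithelial genes had a median of -1.38, between 0 and the motile cilia median of -1.71. Background limits the latter (level 5.72 on the array labelled Gemc1-null, negative-control median 5.74), so the sizes of the 2 falls cannot be compared. Airway secretory genes, also of the airway lining, had a median of -4.35.

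The second pattern is the lower level of motile cilia, ovary and oocyte genes on the oviduct array labelled Gemc1-null. A smaller share of epithelium is argued against by the general epithelium median of 0.08 and the oviduct secretory median of 0.38. Ovary tissue in the WT sample stays open for the ovary and oocyte genes and was not tested apart from their own values: Cyp11a1 was at 12.05 on the WT array and 5.71 on the other, and 8 of 8 ovary somatic and 6 of 7 oocyte genes were above the array's median on the WT array against 5 of 8 and 1 of 7 on the array labelled Gemc1-null. Ovary tissue by itself does not account for the cilia genes, since added ovary would dilute the epithelium of the WT sample. The motile cilia median was -1.75 (quartiles -2.45 and -1.33). Other differences in dissection between the 2 oviduct samples were not tested. The stage of the reproductive cycle, which is not given in the sources used here, has no counterpart in the male tracheas, where the motile cilia median was -1.71, and 0 of 6 estrogen responsive genes were past 2-fold in oviduct (median 0.18), but neither value excludes it for the cilia genes, since the trachea difference is itself open to tissue make-up and the estrogen responsive genes went both ways; with 1 mouse per genotype, genotype and the individual mouse are not separated within oviduct, and the limma fit over both tissues bears only on what they share.

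The third pattern is the higher Gmnc level on the oviduct array labelled Gemc1-null. An effect over the whole locus was examined in the 4 of 11 measured genes within 1 Mb of Gmnc that passed the filter. Their median was 0.18 in oviduct, which argues against a difference as large as that of Gmnc in these 4 genes. Il1rap was the highest at 0.95, though its WT level of 5.61 lay below the negative-control median of 5.77. A smaller or more local effect stays open, since the other measured genes were too low to pass. An exchange of the oviduct labels would make the array with motile cilia genes near background the WT oviduct, a tract lined by multiciliated cells. The 83 genes had a median level of 5.94 there, beside a negative-control median of 5.79, and 8.02 on the array labelled WT. These levels argue against an exchange, though each rests on 1 array, so it is not excluded. In trachea motile cilia genes were also lower on the array labelled Gemc1-null (the higher of the 2 medians was -1.71), but that difference is itself undecided. A transcript of the targeted allele that is read by the 1 probe set of Gmnc remains a possible explanation, and no second probe set is there to tell it from a higher level of the intact transcript.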

How the results depend on the processing

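Counts by size kept within 1.5 times of their value under no level filter, the 75th percentile filter, re-centred arrays, repeated quantile normalization, cyclic loess and the mean of probe sets. The share of lower genes among those past 2-fold stayed between 53.4% and 57.6% in trachea and between 75.5% and 80.8% in oviduct over these and over every probe set on its own. Counting every probe set on its own gave 2582 lower in trachea and 868 lower and 282 higher in oviduct, since more features were counted (65956 in place of 30689). A 1.5-fold threshold gave 2689 lower and 2384 higher in trachea, 1033 and 555 in oviduct, and 426 lower and 82 higher in both; a 3-fold threshold gave 873 and 615, 271 and 35, and 136 and 1, by construction of the threshold. The limma fit gave 0 genes in each direction under every alternative run. Of 295 list medians under alternatives, 290 stayed on their side of the random range, 4 moved out of it without the level filter (regulators and the tuft, ionocyte and neuroendocrine list in trachea, centriole amplification and squamous epithelium in oviduct) and 1, immediate early genes in trachea, moved into it under quantile normalization; the cause was not tested. Of 987 values of named genes 975 kept their side of 2-fold, 5 passed it and 7 fell short of it, and 0 turned their direction while past it; Armcx3 was at 0.92 in trachea and 0.56 in oviduct with the mean of its probe sets. Without the trachea array labelled Gemc1-null no trachea count, overlap or fit remains, and the oviduct counts do not use it. Signals near the negative-control median (5.74 to 5.98) limit how large a fold can appear for genes that are low on an array.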

Other observations

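Many genes lower in both tissues lay outside the cilia lists. Of the 251, 185 were in none of the lists of cilia complexes and regulators, among them Spata18, Rgs22, Cdhr3, Cdhr4, Fam216b and Agr3, picked after their values were seen. The lists do not hold every cilia gene: Cfap46, Cfap47, Cfap69, Drc3 and Drc7 are also among the 185. Absence from the lists therefore does not make a gene unrelated to cilia. Among genes at least 2-fold lower in oviduct the differences of the 2 tissues correlated across genes at Pearson r = 0.567 and Spearman rho = 0.536 (458 genes), and without the cilia lists r over all genes was 0.107. The 458 genes were chosen by 1 of the 2 correlated differences. WT levels of the 2 tissues correlated at r = 0.947 over probe sets, and near background a difference follows the WT level. The r of 0.567 is therefore no measure of a shared response. The genes lower in trachea and higher in oviduct held 46 immunoglobulin segments among 72. Immunoglobulin segments, looked at after the values were seen, had a median of -2.44 in trachea (156 of 173 at least 2-fold lower) and of 0.90 in oviduct (46 of 124 at least 2-fold higher).

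The remaining lists gave smaller or mixed differences. Interferon response genes had a median of -1.05 in trachea (6 of 10 at least 2-fold lower, with Oas1a at -1.67 and Usp18 at -1.59) and -0.30 in oviduct (1 of 8, Usp18 at -1.67). Mx1, counted among the 6, lay below the negative-control median on the trachea array labelled Gemc1-null. Against that median Mx1 was at least 1.85-fold lower, a bound short of 2-fold. Targets of p53 had a median of 0.29 in trachea, with Ccng1 at 1.95 and Trp53inp1 at -1.83, and -0.28 in oviduct, with Cdkn1a at -0.85. Notch pathway genes had medians of 0.13 and -0.04, with Lfng at -1.18 and Jag2 at 1.05 in trachea. Immediate early genes had medians of -0.38 in trachea, with Fosb at -1.04, and 0.00 in oviduct, with Egr1 at -1.23. Estrogen responsive genes of the tract had medians of 0.19 in trachea, with Ltf at -4.40, and 0.18 in oviduct, with Lcn2 at -0.99. Myeloid genes had medians of -0.94 in trachea, with S100a9 at 2.19 and Lyz2 at -2.11, and -0.05 in oviduct. Endothelial genes had medians of -0.61 and -0.29, and tuft, ionocyte and neuroendocrine genes of 0.06 and 0.25, with Cftr at 1.10 in oviduct. In oviduct the basal cell, smooth muscle, fibroblast, cartilage, skeletal muscle and squamous lists had medians of 0.10, 0.09, 0.02, 0.12, 0.01 and 0.21. Thyroid genes had a median of 0.48 in oviduct over 4 members, led by Tshr at 1.03, and 1 member passed in trachea, Slc5a5 at 0.26. In trachea the oviduct secretory list had a median of -0.16, with Muc1 at -3.10, and the ovary somatic list of 0.32, while 1 oocyte gene passed, Ooep at 0.10. The erythroid genes Alas2 and Slc4a1 differed by -0.29 and -0.05 in trachea and by 0.10 and 0.20 in oviduct. Among the sex-linked genes the trachea median was -0.21. In all, 37 of 59 list medians lay outside the central 95% of random lists, where 3 would be expected by chance for lists of unrelated genes, and the members of these lists are known to vary together.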
